A study of Schizosaccharomyces pombe with 144 samples.

How the data were processed

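The series holds 144 samples of fission yeast, and the table analysed here has columns for 10 of them, the total RNA libraries of the meiotic time course. These came from a diploid strain with an analog-sensitive pat1 allele, per the labels. The other 134 samples, which are chromatin immunoprecipitation libraries and their inputs (128) and total RNA libraries of a swi6 chromodomain mutant and its wild type (6), were not analysed here. The comparisons planned for them were not run. Libraries were made with a strand-specific total RNA kit, per the labels' protocols.

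The authors deposited RPKM values, reads scaled to the length of the gene and to the reads of the library, per the file headers, and also columns named TPM. The deposited TPM columns, per the file headers, are not proportional to the RPKM columns within a library and were used for no comparison. The submitters' processing notes name bcl2fastq 1.17, cutadapt 1.18, Bowtie 1.2.2, SAMtools 1.9, bedtools 2.27.1 and 2.26.0 and STAR 2.7.3a, and the builds ASM294v2 and mm10, for the series as a whole. The counting tool, the annotation behind the gene lengths, the use of strand in counting and the treatment of reads that map to several places are not given in the sources used here. Overlapping and antisense genes and near-identical copies are therefore uncertain. All columns of per-sample values were matched to a sample by the stage in its title.

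Gene names were matched to a reference annotation of another build (ASM294v3), used for names, products and exonic lengths only, with no coordinates printed. Of 5157 genes, 4086 matched by symbol, 942 by systematic ID and 102 by a synonym, and 27 did not match. RPKM times exonic length gave, for the lowest genes of each library, multiples of the value of 1 read, from which the number of reads each library was scaled to was estimated (tolerance 0.4%). Lengths differ from the authors' for many genes, so whole counts were not recovered and no count test was run. The search for the step was revised after a first form failed on simulated libraries, and then recovered their depth. The depth estimates relative to 0 h were checked against the ratios between both kinds of deposited column, which gave 0.729 at 6 h, the same as the estimate from the steps.

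Changes are differences of log2(RPKM + 1), which understate the change of low genes. A gene was called higher or lower at 4-fold or more (2 on the log2 scale) with 5 RPKM or more in at least 1 of the 2 libraries compared. This size rule is no test, since there is 1 library per time point. Of 27 gene lists written before the data were examined, 24 had measured members, that is, genes with a mean of 1 RPKM or more over the 10 libraries. The lists of long noncoding and ribosomal RNA had no gene in the table, and the mitochondrial list had 3 genes, none of them measured. The name hrs1 was left out of the bouquet list because it names another gene in this table. Some lists share members, so their results are not separate. The elimination targets share members with the recombination, bouquet and division lists, and the kinase regulators with the division and premeiotic S phase lists. A list's median change is given with its percentile among 10000 random lists of the same size, matched on mean expression in 10 bins, as a description of these libraries. Named genes follow a rule fixed before the data were examined. The rule takes 10 genes in any case, the 4 measured members of each list with the largest change against 0 h, and, outside the lists, the 8 genes with a symbol with the largest rise and the 8 with the largest fall over the course and between mitosis and 0 h. It took 125 genes, of which the text names those that describe each group. A gene taken by the rule is not reported here.

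The calls were tested on simulated data, with Poisson counts for 5157 genes drawn around the 0 h levels. Depths were those of 0 h and 6 h. The 200 genes changed by known folds all had 100 RPKM or more at 0 h. For that comparison, 100% of genes changed 6-fold and 100% of those changed 12-fold were called, and 0 of 50 genes changed 2-fold, 0 of 50 changed 3-fold and 0 of 4957 unchanged genes. This covers counting error and no difference between cultures. Of 200 simulated unchanged lists of 20 genes, 6 lay outside the central 95% of random lists. Both kinds of list were drawn at random from the same genes, so this checks the calculation alone. It does not cover lists of genes that vary together.

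The alternatives tried were pseudocounts of 0.1 and 5, rescaling of each library by the median ratio over genes to the geometric mean library, no filter on low values, a filter of 20 RPKM, protein-coding genes only, mitosis as the reference, and the hour of the highest 3-point running mean. Leaving out 1 h and 2 h, 6 h or 7 h from the count over any hour was added after seeing the data. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.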

Results

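RNA levels were measured by total RNA sequencing in fission yeast diploids that carry an analog-sensitive form of the Pat1 kinase, whose loss of activity starts meiosis. The culture was sampled at 0 h and then every 1 h until 8 h of meiosis, and asynchronous growing cells of the same strain, called mitosis here, gave the remaining library. The table holds 5157 genes in 10 libraries, with 1 library per time point. A difference between time points therefore has no replicate check, no p-value across genes is given, and a gene is called higher or lower only by size, at 4-fold or more. The RPKM values were scaled to an estimated 14998460 reads (6 h) to 20734255 reads (mitosis) per library. At the median exonic length of 1676 bases, 5 RPKM corresponds to 125 reads in the shallowest library, with an exact Poisson 95% interval of 104 to 149 reads that covers counting error only. The median over all genes of the change against 0 h was -0.06 at 4 h, -0.69 at 6 h, -0.78 at 7 h and -0.47 at 8 h on the log2(RPKM + 1) scale, so counts are also given after rescaling each library by its median ratio, which brought these medians to between 0.00 and 0.04.

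The first comparison asks how cells at the start of the meiotic course differed from growing cells. At 0 h the genes of mating and pheromone signalling stood far above growing cells. Of 21 measured members, 20 were 4-fold or more higher, with a list median of 5.71 log2. The M-factor pheromone precursor gene mfm1 read 9074 RPKM at 0 h against 6.52 in mitosis, and mfm3 read 7810.5 against 3.80. The transcription factor gene ste11, which drives sexual differentiation, read 207 against 9.01 RPKM. The RNA-binding protein gene mei2, needed to enter meiosis, read 1239.8 against 14.1 RPKM. Genes of meiotic recombination were already high, with 17 of 19 members 4-fold or more above mitosis and a median of 4.29, against 0.52 for all genes. The meiotic cohesin gene rec8 rose from 2.67 to 222 RPKM. All 11 measured genes listed as targets of meiotic mRNA elimination in growing cells were 4-fold or more higher at 0 h. Of the nitrogen starvation list, 6 of 12 members rose 4-fold or more (5 after rescaling), among them the oligopeptide transporter gene isp4, at 1513 against 16.2 RPKM.

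Ribosomal protein genes moved the other way. Of 141 measured members, 117 were 4-fold or more lower at 0 h than in mitosis (134 after rescaling), with a median of -2.41 and -2.93 after rescaling. The ribosomal P2 gene rpp203 fell from 1319.7 to 60.02 RPKM. The 10 ribosome biogenesis genes had a median of -1.55, with 1 member past 4-fold, the fibrillarin gene fib1, and 6 after rescaling. Outside the lists, the largest increases among genes with a symbol were those of dni2 and shk2, a claudin-like protein and a p21-activated-type kinase, with changes of 8.37 and 8.15 log2. They were followed by mug14 (8.11), meu26 (6.58), mug37 (6.54), the maltase gene agl1 (6.28), the gluconate transporter gene ght3 (6.26) and the DNA repair gene rti1 (6.12). The largest decreases were those of the biotin transporter gene vht1 (-3.47), byr3 (-3.03), the RNA helicase gene dbp3 (-2.97), oga1 (-2.96), the basic amino acid transporter gene cat1 (-2.84), met14 (-2.79), cpc2 (-2.79) and apt1 (-2.76). In all, 459 genes were 4-fold or more higher and 179 lower at 0 h than in mitosis by the size rule. The split rests on the scaling, since 295 genes were higher and 290 lower after rescaling.

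Growing cells were also set against 1 h of meiosis, a pair of stages that some of the chromatin libraries of the series contrast. The mating and pheromone genes remained above mitosis at 1 h, with 19 of 21 members 4-fold or more higher and a median of 4.21. Recombination genes had 18 of 19 members 4-fold or more higher. Ribosomal protein genes lay closer to growing cells than at 0 h, with 6 of 141 members 4-fold or more lower (48 after rescaling) and a median of -1.45, against 0.46 for all genes. Core stress genes had 9 of 13 members 4-fold or more above mitosis, against 6 at 0 h, or 7 and 5 after rescaling. Among heterochromatin factors 1 of 25 passed 4-fold, and 0 after rescaling. This was stc1, named after its values were seen, at 50.4 RPKM against 11.7, while the histone H3 lysine 9 methyltransferase gene clr4 read 18.5 RPKM at 1 h and 6.79 in mitosis. By the size rule 430 genes were higher and 111 lower at 1 h than in mitosis, and 320 and 236 after rescaling.

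RNA was sequenced over the course to judge the synchrony of the cultures from meiotic genes, and the gene groups reached their highest medians in turn. Mating genes were highest at 0 h, recombination genes and histones at 3 h, genes of the meiotic divisions at 5 h, genes of the forespore membrane and spore wall at 6 h, and the wtf family at 8 h. After rescaling, the hour of the division genes became 6 h and the others named here kept theirs. Members did not all follow their median, since 7 of 12 division genes had their highest RPKM at 6 h and 2 at 5 h, and 5 of 18 spore wall genes had it at 8 h and 3 at 6 h.

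**Figure D1:**
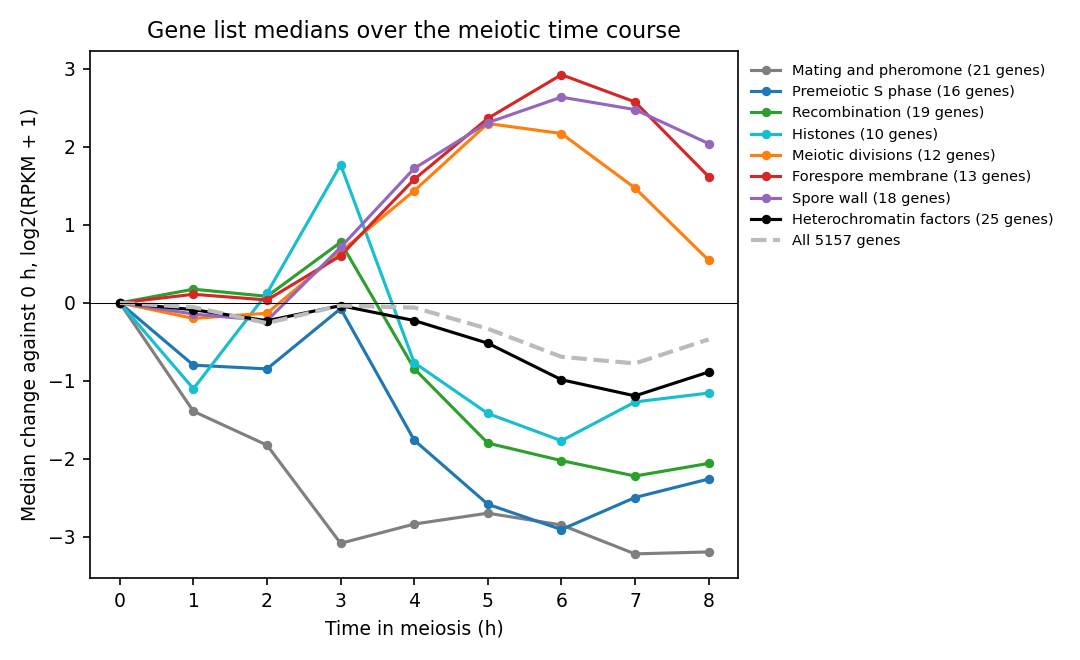
Median over each gene list of log2(RPKM + 1) minus its value at 0 h (vertical axis) against hours in meiosis (horizontal axis), with 1 library per point and the median of all 5157 genes as a dashed line. The forespore membrane list peaks at 6 h at 2.93, while the recombination list goes from 0.78 at 3 h to -1.80 at 5 h.

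Mating genes fell from their 0 h levels, and members of the nitrogen starvation list went both ways. Of the 21 mating and pheromone genes, 19 were 4-fold or more lower at some hour (18 after rescaling), and the list median was -3.08 at 3 h and -3.22 at 7 h. The median lay below those of all 10000 random lists of matched expression at each hour from 1 h. The pheromone genes mfm3 and mfm1 fell to 146 and 243 RPKM at 3 h, the carboxypeptidase gene sxa2 from 2072 to 53.4, and the M-factor receptor gene map3 from 708 at 0 h to 22.8 at 7 h. The gene ste11 fell to 21.3 RPKM at 7 h and mei2 to 213, the latter under 4-fold after rescaling. At 7 h all genes had a median of -0.78, and the mating list stood at -2.42 after rescaling. In the nitrogen starvation list 8 of 12 members fell 4-fold or more at some hour (5 after rescaling) and 3 rose so at some hour in both scalings. Of those that fell, isp4 fell from 1513 to 48.5 RPKM within 1 h and the ammonium transporter gene amt1 from 162 to 6.43 at 2 h. The copper transporter gene ctr4 fell to 17.6 RPKM at 1 h. The invertase gene inv1 rose from 34.8 to 345 RPKM at 2 h and fell to 6.79 at 5 h, a fall that was under 4-fold after rescaling. The others that rose were the acid phosphatase gene pho1, which is also in the phosphate and thiamine list, and the autophagy gene atg8. The latter, named after its values were seen, read 233 RPKM at 0 h and 1526 at 8 h. The list mixes genes of several nutrients, so its split is not one of nitrogen genes alone.

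Genes of premeiotic DNA synthesis, most of them regulated at the G1 to S transition, were high at 0 h and again at 3 h. Of the 16 members, 8 had their highest RPKM at 0 h and 7 at 3 h. The replication licensing gene cdc18 read 292 RPKM at 0 h, 63.3 at 1 h, 138 at 3 h and 16.8 at 4 h. The ribonucleotide reductase gene cdc22 followed a like course, at 1861, 323, 893 and 146 RPKM. At 6 h 11 members were 4-fold or more below 0 h (9 after rescaling), among them dut1 at 15.9 RPKM and cdt1 at 6.62, and the median was -2.91, or -2.19 after rescaling. All 10 measured histone genes had their highest RPKM at 3 h, and 4 of them, hta2, hht1, hhf1 and hhf3, rose 4-fold or more in both scalings, hta2 and hhf1 being named after their values were seen. The histone H3 gene hht1 read 448 RPKM at 0 h, 3549 at 3 h and 489.8 at 4 h, and the H4 gene hhf3 352, 2069 and 179. The H2A gene hta1 was at 1102 RPKM at 3 h and fell to 63.0 at 6 h, and the H2A.Z gene pht1 to 38.3, and after rescaling pht1 passed 4-fold at 5 h alone, at -2.01. Most histone genes of this list are near-identical copies, so the share of each such copy is uncertain.

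Recombination genes as a group were highest at 3 h and lower from 4 h on. Of 19 members, 13 were highest at 3 h, where the median was 0.78 (percentile 100 among random lists). At 8 h 12 members were 4-fold or more below 0 h, but 5 after rescaling, against 9 and 8 at 5 h and 12 and 9 at any hour. The gene rec8 read 248 RPKM at 3 h and 16.5 at 5 h, rec15 381 and 15.2, and the kinase gene mek1 171 and 13.5. The gene mde2 was an exception and rose from 8.77 RPKM at 0 h to 297 at 6 h. Genes of the bouquet and horsetail movement were highest at 1 h, with a median of 0.38, and 6 of 9 were 4-fold or more lower at 7 h, but 0 after rescaling. The telomere bouquet gene bqt1 fell from 72.8 at 0 h to 10.2 RPKM at 5 h, the dynein light chain gene dlc1 from 249 to 41.0 at 6 h, the dynein anchor gene mcp5 from 88.2 to 14.3 at 7 h and kms1 from 63.5 to 11.1 at 6 h. Of these falls, those of dlc1, mcp5 and kms1 were under 4-fold after rescaling. In the list of elimination targets, which shares members with the recombination, bouquet and division lists, 7 of 11 were 4-fold or more lower at 7 h. After rescaling 3 were. Its member mug9 fell from 215 to 15.6 RPKM at 6 h and mug8 from 413 to 37.1 at 7 h. The meiotic cyclin gene rem1 rose from 6.45 to 209 RPKM at 6 h.

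Genes of the meiotic divisions rose in mid-course. At 4 h 4 members were 4-fold or more above 0 h, and at 5 h 7 of 12 members were so (9 after rescaling), with a median of 2.30, above all 10000 random lists. The forkhead factor gene mei4, which drives middle meiotic transcription, read 88.8 RPKM at 0 h and 347 at 5 h, a change of 1.96 that stays just under the 4-fold limit and passes it after rescaling, at 2.30. The kinase gene spo4 and spo6, which encodes its regulatory subunit, rose from 31.4 and 111 RPKM at 0 h to 1457 and 2549 at 6 h. The gene mes1, an inhibitor of the anaphase-promoting complex, rose from 85.1 to 549 RPKM at 6 h, and mfr1, an activator of that complex, from 11.5 to 559 at 7 h. Forespore membrane genes were highest at 6 h, where 9 of 13 members were 4-fold or more above 0 h (11 after rescaling) and 9 had their highest RPKM. The leading edge gene meu14 rose from 48.8 to 2225 RPKM, the septin genes spn5 and spn6 from 58.6 and 50.7 to 1701 and 1031, and spo3 from 13.3 to 295 at 7 h. In the spore wall list 10 of 18 members were 4-fold or more higher and 3 lower at 6 h (11 and 2 after rescaling). The spore coat gene isp3 rose from 6766 RPKM at 0 h to 78239.8 at 6 h and 134840 at 8 h. The amylase-family gene mde5 reached 4489.9 RPKM and the glucanase gene agn2 5292 at 8 h, and the glucan synthase gene mok14 2659 at 7 h, from 58.3, 98.4 and 49.5 at 0 h. The oxygenase gene isp7 of this list fell from 319 to 6.30 RPKM at 2 h.

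**Figure D2:**
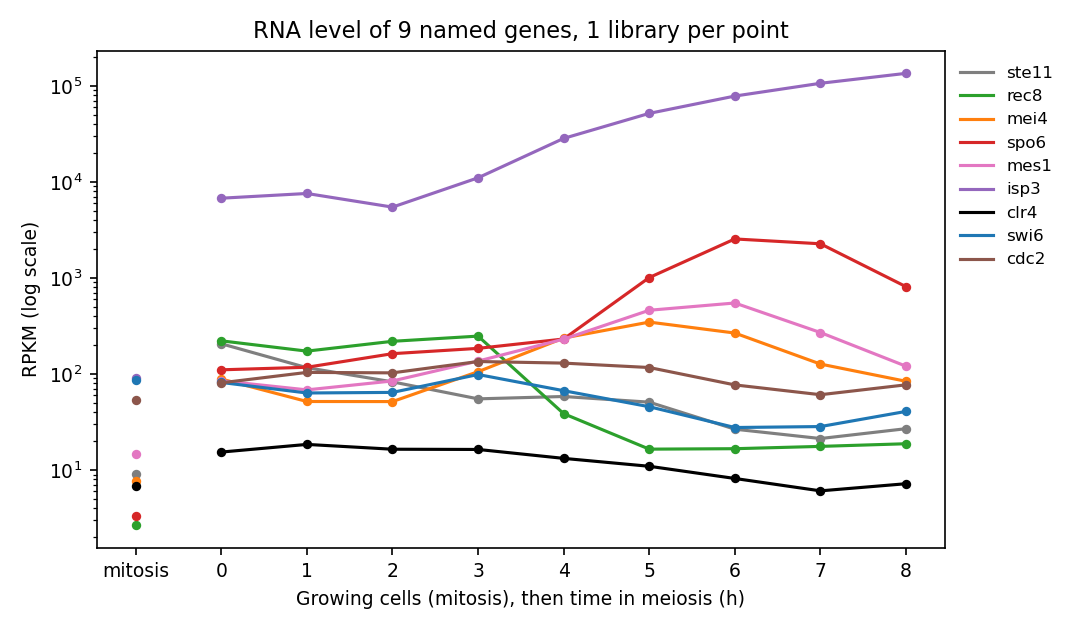
RPKM on a log axis of 9 genes that were to be reported in any case, in growing cells (left) and at each hour of meiosis, with 1 library per point. The gene rec8 goes from 248 RPKM at 3 h to 16.5 at 5 h while spo6 goes from 185 to 1010.3, and isp3 reaches 134840 at 8 h.

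No gene of heterochromatin formation rose 4-fold at any hour, and 2 of 25 were 4-fold or more lower at some hour, against 0 after rescaling. These were the poly(A) polymerase gene cid12, at 28.7 RPKM at 0 h and 5.25 at 7 h, and the silencing gene clr2, at 21.7 and, at 6 h, 4.56. The level of clr4 was 15.4 RPKM at 0 h, 18.5 at 1 h and 6.09 at 7 h, and that of swi6, which encodes the heterochromatin protein that binds methylated histone H3 lysine 9, was 81.8, 63.5 and 28.4. The genes sir2 and ago1 read 28.9 and 80.8 RPKM at 0 h and 7.01 and 21.1 at 7 h. The list median at 7 h was -1.19, at percentile 9.67 among random lists, against -0.78 for all genes, and it was -0.44 after rescaling. At 8 h it was -0.89, at percentile 3.67, against -0.47 for all genes, and -0.36 after rescaling. The percentiles are for RPKM as deposited, in which all 25 members were below 0 h at both hours. The cyclin-dependent kinase gene cdc2 read 81.1 RPKM at 0 h, 135 at 3 h and 61.0 at 7 h, all within 4-fold. Its change at 7 h was -0.41 as deposited and 0.44 after rescaling, so the direction there rests on the scaling. Among the 20 genes of the kinase and its regulators, 4 rose and 5 fell 4-fold or more at some hour, and 7 and 1 after rescaling. The cyclin gene cig1 fell from 56.1 to 7.37 RPKM at 7 h, and after rescaling it passed 4-fold at 6 h alone, at -2.01. None of the 8 measured mRNA elimination factors passed 4-fold at any hour in either scaling, and pab2, at 98.3 RPKM at 0 h and 25.4 at 6 h, came closest, followed by pla1 at 94.5 and, at 7 h, 32.6. The genes red1 and mtl1 read 75.1 and 22.5 RPKM at 0 h and 31.1 and 10.4 at 7 h, changes of -0.41 and -0.25 after rescaling. The median of the elimination factors at 7 h was -0.92, at percentile 42.1 among random lists, against -0.78 for all genes. After rescaling it was -0.12.

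Ribosomal protein genes, low at 0 h, had a list median above 0 h at each later hour in both scalings. It was 1.42 at 2 h, 1.42 at 4 h and 0.31 at 7 h, and 1.70, 1.51 and 1.16 after rescaling. The size of the drop by 7 h therefore rests on the scaling. In this list 11 of 141 genes rose 4-fold or more at some hour (33 after rescaling), including rpp203, rpl3002, rpl2702 and rpl1603, which read 439, 395, 1139.7 and 40.7 RPKM at 4 h against 60.02, 60.7, 188 and 6.43 at 0 h. Most of these genes have a near-identical copy. Ribosome biogenesis genes had a median of 0.39 at 4 h, and the nucleolin gene gar2 alone passed 4-fold, as it fell from 382 to 53.4 RPKM at 6 h. Among glycolytic and housekeeping genes, 3 of 11 were 4-fold or more lower at 2 h in both scalings, with tdh1 at 372, pyk1 at 278 and fba1 at 927 RPKM against 2082, 1445 and 4671 at 0 h. In the core stress list 3 of 13 members rose and 4 fell 4-fold or more at some hour (5 and 4 after rescaling). The small heat shock gene hsp16 rose from 79.6 to 2962 at 1 h and 6440.1 RPKM at 2 h and returned to 207 at 3 h. The sulfiredoxin gene srx1 rose to 375 RPKM at 1 h from 36.7, while hsp9 fell from 5417 to 206 at 2 h and sro1 from 319 to 29.5 at 7 h. The iron list had its highest median at 2 h, at 0.27, where the siderophore transporter gene str1 rose from 32.9 to 169 RPKM. Its member str3 was at 33.6, 6.58 and 68.6 RPKM at 0 h, 1 h and 2 h. The acid phosphatase gene pho1 rose from 381 to 2611 RPKM at 2 h, and the phosphate transporter gene pho84 fell from 593 to 84.8 at 6 h. The phosphate and thiamine list had a median of -1.71 at 7 h, or -0.89 after rescaling. Of 14 genes of vegetative cell division, 1 rose and 4 fell 4-fold or more at some hour (2 and 2 after rescaling). The glucanase gene agn1 fell from 228 to 10.5 RPKM at 7 h, while adg2 rose from 241 to 3044 at 4 h. The gene adg1 fell from 16.8 RPKM at 0 h to 2.94 at 2 h, which was under 4-fold after rescaling.

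Repeated families took separate courses, with the caution that reads of near-identical copies cannot be assigned to one copy with certainty. The wtf genes, a family that includes spore killers, rose late. At 8 h 22 of 25 were 4-fold or more above 0 h (23 after rescaling) and 23 had their highest RPKM, with a median of 2.95. The members wtf4, wtf7 and wtf13 read 599.9, 294 and 427 RPKM at 8 h against 40.6, 18.2 and 33.8 at 0 h, and wtf23 reached 354 at 6 h. None of the 13 Tf2 retrotransposons passed 4-fold at any hour in either scaling, although each was highest at 1 h, with a median of 0.78. Tf2-11 read 11.3 RPKM at 0 h, 20.4 at 1 h and 3.60 at 7 h. Of 86 subtelomeric genes in the table, 42 were measured. They were mixed, with 11 of 42 members 4-fold or more higher and 3 lower at 8 h, the same counts as after rescaling. A gene silent at most hours counts as measured only through its high hours, which favours rises in this share. SPBC1348.07 and SPBPB2B2.14c rose to 90.01 and 71.7 RPKM at 8 h, SPBPB2B2.08 read 197 at 2 h and SPAC977.15 652 at 1 h, from 1.76, 1.12, 0.337 and 13.9 at 0 h. Both measured mating-type genes, mat1-Mc and mat3-Mc, fell from 537 and 848 to 48.7 and 73.2 RPKM at 7 h and are copies of one sequence.

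Outside the lists, the largest rise among genes with a symbol was that of mug146, from 3.49 RPKM at 0 h to 1231 at 8 h. The genes mug103, the proton pump gene pma2, the channel gene trp663 and erf4 also had their largest change at 8 h, at 7.05, 6.87, 6.55 and 6.18 log2. The amylase-family gene meu7 reached 19538 RPKM at 7 h from 157, and meu25 1569.8 from 20.8. The copper-dependent transcription factor gene cuf2 reached 573 RPKM at 6 h from 5.46. Among the same genes, the largest fall was that of the proline transporter gene put4, from 111 to 1.58 RPKM at 2 h. Next came shk2, dni1 and dni2, at -5.31, -4.79 and -4.67 log2 at 3 h. They were followed by mug37 (-4.09 at 6 h), agl1 (-4.07 at 5 h), the arrestin-family gene ste7 (-3.89 at 7 h) and tos4 (-3.88 at 5 h).

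Genes that stood 4-fold or more above both neighbouring hours were mostly found early, with 22 at 1 h, among them srx1 and SPAC977.15, and 22 at 2 h, among them SPBPB2B2.08 and str3. Over all genes, 390 were 4-fold or more higher and 674 lower than at 0 h at 1 or more hours, and 592 and 241 after rescaling. The hourly counts of higher and lower genes were 65 and 59 at 1 h, 58 and 93 at 2 h, 34 and 73 at 3 h and 94 and 96 at 4 h. They were 156 and 246 at 5 h, 208 and 531 at 6 h, 183 and 510 at 7 h and 199 and 237 at 8 h. Rescaling turned the balance at 2 h (92 higher and 68 lower) and from 4 h on, to 101 and 80 at 4 h, 221 and 137 at 5 h, 360 and 156 at 6 h, 355 and 108 at 7 h and 289 and 101 at 8 h. Of the 459 genes higher at 0 h than in mitosis, 188 were 4-fold or more below 0 h at some later hour and 104 above it. Among all 5004 genes with 5 RPKM or more at some hour of the course, 674 were below and 390 above. The 459 were chosen by their level at 0 h, which is also the reference, so falls are favoured. The later course of these genes was not counted after rescaling.

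**Figure D3:**
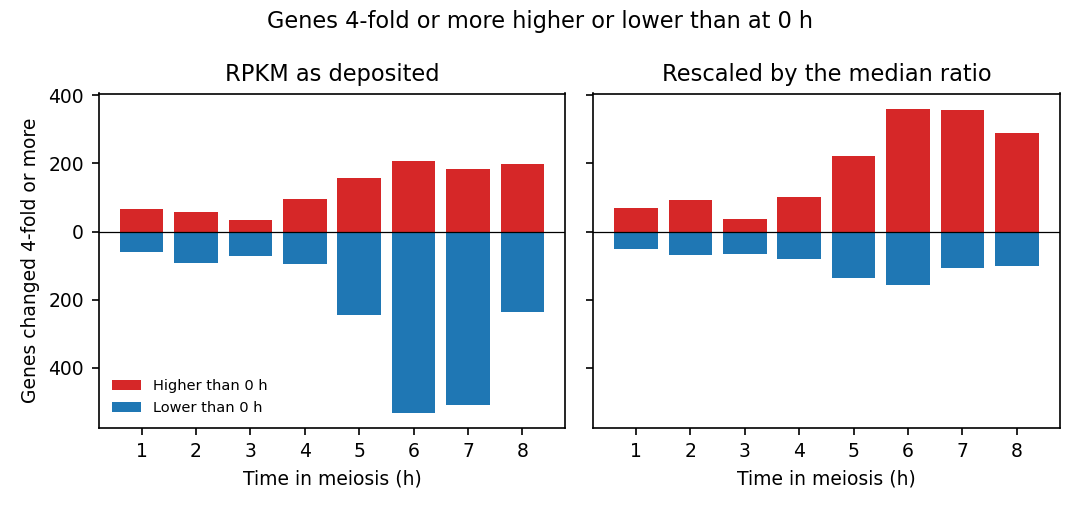
Number of genes 4-fold or more higher (red, upwards) or lower (blue, downwards) than at 0 h at each hour of meiosis, with RPKM as deposited (left) and after rescaling by the median ratio (right). At 7 h the counts are 183 higher and 510 lower on the left and 355 and 108 on the right.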

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

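The tests of the TPM columns, the depth test at 7 h and the tests of counting noise and of the order of 1 h and 2 h were chosen only after the result was seen. The last of these replace earlier tests whose outcome the choice of genes had settled. In the columns named TPM, which no comparison uses, the ratio to the RPKM column took 10 distinct values within each library, up to 1.72-fold apart, and column sums ran from 773446 to 1315310. A different gene length in the 2 kinds of column would give each gene the same step in all 10 libraries, but 0% of genes had that. Dividing by library totals along rows instead of columns accounts for 100% of the values above 1 RPKM within 0.1%, and 10.004% of values had the total of their own library. That library totals were divided along the rows instead of along the columns is the candidate explanation, and no biological explanation was tested.

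Most genes had a lower RPKM at 7 h than at 0 h, with a median of -0.78 on the log2 scale. The estimated reads at 7 h were 1.01 times those of 0 h. This ratio decides nothing here, since RPKM is already scaled to the reads of the library. The 183 genes that rose 4-fold or more took 39.1% of the estimated reads at 7 h and 2.17% at 0 h (Wilson 95% intervals, counting error only, 39.10 to 39.15% and 2.17 to 2.18%). With them taken out of both totals the median of the other genes went from -0.82 to -0.18, just inside the bound of -0.2. The same step at 6 h gave -0.21, just outside it. The bound was set before this test, with the medians of all genes and the levels of isp3 already seen. The genes were chosen for their rise in this same contrast, so taking them out had to raise the median. The size of the move follows from their shares, so the bound decides nothing about the cause. Within these scaled values, the share taken by these genes may account for most of the shift. A fall in RNA per cell stays open, as no biological explanation was tested.

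At 1 h and at 2 h, 22 genes each stood 4-fold or more above both neighbouring hours, against 2 genes at 3 h, the histone genes hhf3 and hht3 (the latter named after its values were seen), and 0 at each hour from 4 h to 7 h. Counting noise is argued against, since it acts on all libraries alike and 0 genes were so at 4 h to 7 h, which include the shallowest library. An exchange of both libraries would leave most of these peaks in place at the other hour. The order of both libraries therefore bears on the hour of the peaks and not on their origin. In 83.2% of the 107 genes 4-fold apart between 0 h and 3 h, the 1 h level lay on the 0 h side of the 2 h level. The Wilson 95% interval, over genes that are not independent, was 74.97 to 89.09%, which includes the bound of 80% set before this count. A return towards growing cells is argued against as the source of these peaks, since 2.273% of these genes reached 50% of their high level in mitosis. This covers the genes with a peak only. Genes that moved towards growing levels and stayed there could not enter the count. Ribosomal protein genes did move that way, from a median of -2.41 against mitosis at 0 h to -1.45 at 1 h. A response to the handling of the culture and a difference in how these libraries were made stay open, because 1 library per hour and no untreated culture were analysed here.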

How the results depend on the processing

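Without 1 h and 2 h, a choice made after seeing the data, 305 genes were 4-fold or more higher and 638 lower at any hour; leaving out 6 h or 7 h was also added then and gave 366 or 389 higher and 576 or 607 lower. Counts of changed genes stayed within 1.5 times with no filter, with a filter of 20 RPKM, with protein-coding genes only and with a pseudocount of 0.1. A pseudocount of 5 gave 159 lower genes at 5 h, 326 at 6 h, 299 at 7 h and 397 at any hour. Rescaling by the median ratio gave 92 higher genes at 2 h, 360 at 6 h, 355 at 7 h and 592 at any hour. It gave 137 lower genes at 5 h, 156 at 6 h, 108 at 7 h, 101 at 8 h and 241 at any hour. At 0 h against mitosis it gave 295 higher and 290 lower genes, and at 1 h against mitosis 236 lower. These moves follow from the shift that the rescaling removes. Against mitosis in place of 0 h, another contrast by construction, 430 (1 h), 400 (2 h), 394 (3 h), 424 (4 h), 452 (5 h), 481 (6 h), 440 (7 h) and 484 (8 h) genes were higher, and 935 at any hour, while 111 (1 h), 181 (2 h) and 61 (4 h) were lower. Among list medians past 4-fold at their hour of largest change, those that changed sign with this reference were at 7 h and stood at 2.42 for mating, 2.35 for recombination, 1.31 for the bouquet, 2.35 for elimination targets and 0.86 for the mating-type genes. The elimination targets share members with the recombination and bouquet lists. Medians under 4-fold also changed sign with it for the kinase regulators at 7 h, nitrogen starvation and iron at 6 h, ribosomal proteins at 4 h and core stress at 2 h, and with rescaling for the kinase regulators and ribosome biogenesis at 7 h.

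The hour of the highest list median moved for some lists, and the cause was not tested. Rescaling moved it to 3 h for premeiotic S phase and heterochromatin factors, 6 h for the divisions and glycolysis, 8 h for the kinase regulators and core stress, 2 h for ribosomal proteins and 1 h for phosphate and thiamine. Mitosis as the reference moved it to 3 h for premeiotic S phase, 1 h for heterochromatin factors, elimination targets and core stress, 4 h for elimination factors, 5 h for the kinase regulators, 2 h for ribosomal proteins and 0 h for subtelomeric genes. The 3-point running mean moved it to 2 h for recombination, the bouquet and elimination targets, 6 h for the divisions, 4 h for the kinase regulators, 3 h for ribosomal proteins and ribosome biogenesis, 5 h for glycolysis, 1 h for iron and 0 h for subtelomeric genes and Tf2. A pseudocount of 0.1 moved it to 1 h for elimination targets. No named gene's value or list median past 4-fold changed sign with a pseudocount or the rescaling, but this is no check. A pseudocount keeps the sign of each gene, and the rescaling shifts are below 2 log2. Of 274 values of named genes and list medians, 228 moved with rescaling, 165 with a pseudocount of 5 and 47 with 0.1. Moved means past counting error for a gene, or past a bootstrap interval over members for a list. No paired analysis was possible because each time point has 1 library. Of the 47 alternatives chosen before the data were examined, 22 belong to libraries not analysed here and were not run. Depth limits genes near 5 RPKM, where counting error alone spans 104 to 149 reads around 125.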

Other observations

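The genes named here were chosen after their values were seen. Genes 4-fold or more above both hours next to 1 h include the glucose transporter gene ght1, at 525 RPKM against 24.1 at 0 h and 23.5 at 2 h. The gene zwf2, which encodes a glucose-6-phosphate dehydrogenase, read 1572 against 92.9 and 78.8. It read 451 RPKM at 3 h, so it was not high at 1 h alone. The heat shock gene ssa1 was at 3556 RPKM at 1 h against 267 at 0 h and 374 at 2 h, and the quinone reductase gene obr1 at 1867 against 186 and 277.

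Among the genes 4-fold or more above both hours next to 2 h, the arylsulfatase gene SPBPB10D8.02c read 0.958 RPKM at 1 h, 434 at 2 h and 6.61 at 3 h. The sulfate transporter gene SPAC869.05c read 56.9, 923 and 24.7 RPKM at these hours, and the cysteine transporter gene SPCPB1C11.03 43.3, 748 and 34.1. The homocysteine synthase gene met17 read 334, 1376 and 72.2 RPKM, the S-adenosylmethionine synthetase gene sam1 504, 2765 and 542, and the glutathione transporter gene pgt1 20.3, 245 and 13.7. At 0 h met17 read 19.9 RPKM, so its rise had begun at 1 h. No enrichment of a pathway was tested.

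Across genes within the course, neighbouring hours correlated least between 0 h and 1 h (Pearson's r 0.914 across genes, which are not independent replicates) and most between 6 h and 7 h (0.979).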
